A study of Mus musculus with 12 samples.

How the data were processed

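The values used were the FPKM deposited by the authors, gene by gene for each of 12 libraries, which the submitters' processing notes attribute to Cufflinks on the mouse genome GRCm38. The aligner, the versions of these programs and the annotation release are not given in the sources used here. Per the labels, tumours were snap frozen and poly-A RNA was made into libraries with a PrepX kit on an Apollo 324 system and sequenced on an Illumina HiSeq as single-end reads of 75 nt. Read counts were not used here, so the number of fragments behind each library was estimated from the confidence intervals that accompany each FPKM. Reads were not analysed here.

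Each table held 27040 entries, of which 404 had no gene name and 26636 were used by name. The 880 short RNAs (a span under 200 nt, or a microRNA or small nucleolar RNA name) and 138 genes marked as failed in any library were left out, because FPKM of very short transcripts and failed estimates are unreliable. FPKM were scaled between libraries by the median of ratios to the geometric mean, with factors of 0.853 to 1.07, and genes with a mean scaled FPKM of at least 1 over the 12 libraries were kept, which left 12848. A linear model with the 3 groups was fitted to log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3, with eBayes and its trend option, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Count-based models were not used because they need counts. For Mtdh, Snd1, Tap1 and Tap2 an exact two-sided permutation test of the 8 libraries compared was run as well. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

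The 32 gene lists, with 679 members of which 667 were found in the tables (4 under another symbol), were written before the data were examined, as were the alternatives named below unless stated otherwise and the rule for naming genes. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The rule named, per comparison against vehicle and direction, up to 12 genes past the threshold with the largest fold change, filled to 5 by the smallest unadjusted p where fewer passed. For C26A6 against tamoxifen it named up to 6, filled to 3, for both treatments up to 10 with the largest mean change, per list and comparison up to 4 measured members with the smallest p, and always Mtdh, Snd1, Tap1 and Tap2. Unnamed predicted genes, pseudogenes and variable segments of immune receptors were counted but not named. The text gives those of the named genes that its comparisons needed.

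The alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, FPKM as deposited, upper-quartile scaling or quantile normalization, only the 2 groups compared in the fit, library weights, eBayes without trend or robust, short RNAs and failed genes kept, the replicate number as a block, and leaving out each of the 12 libraries in turn. Added after the data had been seen were leaving out together the library of each group farthest from its group mean on the first principal component, 3 in all, the adipocyte level as a covariate, and leaving out genes at overlapping loci.

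The fit was tried on simulated values for 12848 genes in 5 rounds, with the spread within groups pooled over all 12 libraries and changes put into the C26A6 group. Of genes changed by 0.5, 1, 2 and 4 on the log2 scale, 8%, 63.6%, 94.8% and 100% were called, and 5.18% of the calls were unchanged genes. With no change put in, which was tried for tamoxifen against vehicle, 0 genes were called. A list raised by 0.5 was called in every round, and 0 other lists were called. The simulated values were drawn independently for each gene, while in the data the estimated correlation was 0.711 for the interferon list. The rounds therefore do not show how often the list test errs when genes are correlated.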

Results

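Gene expression was measured by sequencing of poly-A RNA from mammary tumours of female mice of the inbred FVB/N strain. The mice carried MMTV-PyVT, a transgene that drives the polyoma virus middle T oncogene in the mammary gland, together with a tamoxifen-inducible Cre recombinase (UBC-CreERT) and floxed alleles of Mtdh, the gene of metadherin. The 12 libraries fell into 3 groups of 4. The first group received C26A6 at 15 mg/kg, a compound that the labels describe as disrupting the contact between Mtdh and its partner protein Snd1. The next received tamoxifen at 60 mg/kg, which activates the recombinase and deletes Mtdh, and the last received a vehicle of corn oil and saline. All were dosed daily for 5 days, and tumours were taken 2 days after the last dose. The labels number 4 replicates per group without stating how many mice gave them and name no batch, so the p-values measure the spread between these tumour samples.

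Expression was given as FPKM, which counts fragments relative to transcript length and library size. Summed FPKM per library lay between 511415 and 684065, and 12045 to 13134 genes per library reached 1 FPKM. The confidence intervals deposited with the values implied a depth of about 12100000 to 21600000 fragments. Fold changes are differences of log2(FPKM + 1), a scale that understates changes of genes with low values. Vehicle replicate 3 stood apart in non-coding RNA, with a scaled FPKM of 972 for Rn18s, 299 for Rn45s and 1146 for Rn7sk, against at most 57.9, 98.9 and 107 in the other libraries. Correlations of log2 values were 0.899 to 0.971 within groups and 0.860 to 0.963 between groups. The first principal component held 26.5% of the variance and did not separate the groups, while on the second, with 18.4%, the 4 vehicle libraries were negative and the 8 treated libraries positive.

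Mtdh was examined first, because tamoxifen was given to delete it. The gene lies on chromosome 15 at 34082719 to 34142385 (GRCm38, coordinates of the deposited tables), and the deleted exon is not given in the sources used here, so its FPKM covers the whole gene. Mtdh stood at 85.03 ± 9.46 FPKM with vehicle and 18.6 ± 4.06 FPKM with tamoxifen (mean ± SD, n = 4 each), which left 21.9% of the vehicle level. The fall was -2.15 on the log2 scale (SE 0.20, limma adjusted p = 2.786e-04), with every tamoxifen library below every vehicle library (exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). With C26A6, Mtdh stood at 98.0 ± 25.4 FPKM, 0.17 above vehicle on the log2 scale with a 95% interval of -0.27 to 0.61 (limma adjusted p = 0.666). Another locus, LOC100503407, is annotated within Mtdh and could share its reads.

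Snd1, which encodes the protein that Mtdh binds, lies on chromosome 6 at 28480348 to 28888832 and also overlaps another annotated locus. It stood at 37.8 ± 2.25 FPKM with vehicle, 32.1 ± 4.50 with C26A6 and 30.1 ± 4.53 with tamoxifen. Its log2 differences from vehicle were -0.24 (SE 0.14, limma adjusted p = 0.354) with C26A6 and -0.33 (SE 0.14, adjusted p = 0.229) with tamoxifen, and neither passed the threshold over all genes. The exact permutation p was 0.0857 for C26A6 and 0.0286, the smallest possible, for tamoxifen. Without tamoxifen replicate 2 the tamoxifen difference was -0.22.

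Tap1 and Tap2 encode the subunits of the transporter that loads peptides onto MHC class I molecules. Tap1 rose from 14.3 ± 2.55 FPKM with vehicle to 34.9 ± 12.1 with C26A6 (log2 1.17, SE 0.235, limma adjusted p = 0.0186) and 31.2 ± 6.22 with tamoxifen (log2 1.06, SE 0.235, adjusted p = 0.0375). Tap2 rose from 17.3 ± 1.73 to 28.9 ± 5.42 FPKM with C26A6 (log2 0.69, SE 0.15, adjusted p = 0.0264) and stood at 24.8 ± 2.95 with tamoxifen (log2 0.49, SE 0.15, adjusted p = 0.105). In each of these 4 comparisons all treated libraries lay above all vehicle libraries. The calls were close to the threshold. With C26A6, Tap1 lost it without C26A6 replicate 2 or vehicle replicate 3 (adjusted p 0.0085 to 0.0737 over all alternatives) and Tap2 without C26A6 replicate 1, 2 or 3 or any vehicle replicate (0.01 to 0.0909), and with tamoxifen Tap1 lost it without any single tamoxifen or vehicle replicate (0.0081 to 0.113). Tap2 also overlaps another annotated locus.

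**Figure D1:**
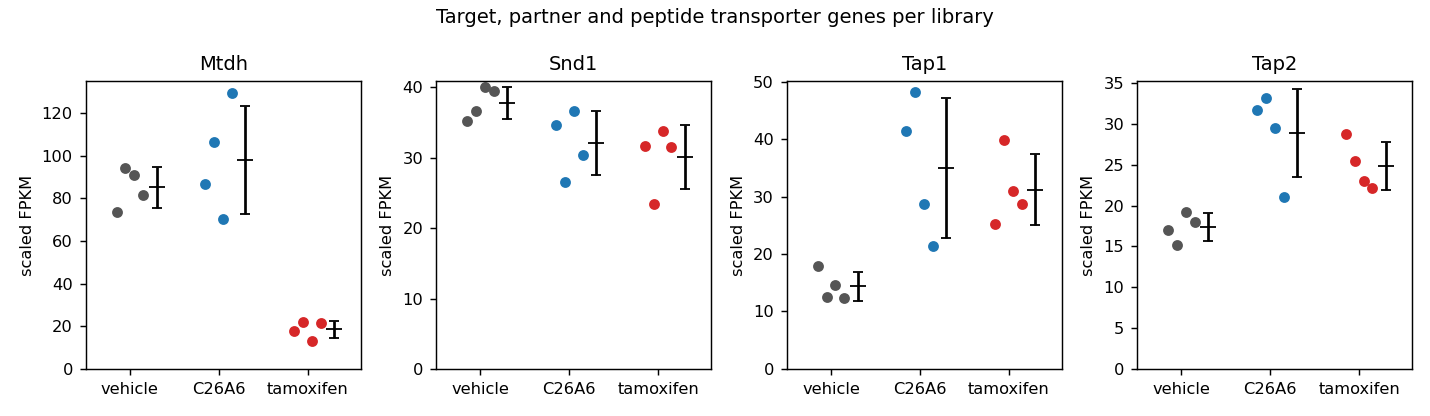
Scaled FPKM of Mtdh, Snd1, Tap1 and Tap2 by group, with 1 point per library and bars for the mean ± SD of 4 libraries. The 4 tamoxifen libraries lay at 13.2 to 21.8 FPKM of Mtdh, below the vehicle range of 73.4 to 94.3.

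The comparison of C26A6 with vehicle asked how the tumour transcriptome changed under the compound. Genes of DNA replication and mitosis fell, as did genes of cholesterol synthesis and haemoglobin transcripts, while some genes of the p53 response (4 of 24), the interferon response (3 of 41) and milk secretion (4 of 16) rose. As lists, cholesterol synthesis and erythroid genes held with an estimated correlation between genes, and replication, mitosis, p53, interferon and milk did not (adjusted p between 0.146 and 0.356). With fry, adjusted p was 0.0019 for replication, 0.0059 for mitosis, 0.007 for p53 and 0.0145 for milk. It was 4.343e-04 for heat shock and 0.013 for immediate early genes. Fry gave 0.0595 for interferon, 0.112 for MHC class I and 0.261 for fibroblast genes, which did not pass. Of 12848 genes tested, 583 passed the threshold, 224 higher and 359 lower with C26A6, and 247 of them changed more than 2-fold. With the FPKM as deposited, 714 passed, 162 higher and 552 lower. The count varied with the libraries used: it was 223 without C26A6 replicate 2, 361 without C26A6 replicate 3, 206 without vehicle replicate 1 and 128 without vehicle replicate 3. The highest count with 1 library left out was 713. A smaller group also lowers the power to call genes, which was not separated from the influence of single libraries.

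In the cholesterol synthesis list, 12 of 22 measured genes fell and none rose (17 lower adjusted over the list alone; median log2 -0.71, adjusted p = 1.635e-17). This call held with an estimated correlation between genes (adjusted p = 0.0264). Idi1, which makes an isoprenoid precursor of sterols, fell from 65.5 ± 10.5 to 14.9 ± 3.25 FPKM (log2 -2.08, SE 0.20, adjusted p = 2.859e-04). Fdps, the farnesyl diphosphate synthase, fell from 105 ± 17.2 to 41.0 ± 6.75 FPKM (log2 -1.33, SE 0.15). Dhcr24, the last reductase of the pathway, fell by 1.77 and Stard4, a sterol carrier, by 1.56 on the log2 scale. These 4 genes passed the threshold under every alternative tried.

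In the list for G1/S and DNA replication, 26 of 35 genes fell (35 adjusted over the list alone; median log2 -1.10, adjusted p = 2.671e-28), though with an estimated correlation the call was lost (adjusted p = 0.146). In the list for G2/M and mitosis, 24 of 36 fell (36 adjusted over the list alone; median log2 -1.18, adjusted p = 5.566e-27), again lost with an estimated correlation (adjusted p = 0.167). Uhrf1, which maintains DNA methylation at replication, fell from 19.4 ± 5.06 to 4.82 ± 2.41 FPKM (log2 -1.88, SE 0.30), and Gins1, part of the replicative helicase, from 9.92 ± 1.28 to 3.16 ± 0.773 FPKM (log2 -1.40, SE 0.21). Cyclin A2 (Ccna2, at a locus that overlaps another) fell by 1.51, Melk by 1.52 and the checkpoint kinase Bub1b by 1.55 on the log2 scale. All 5 passed under every alternative run for them, which for Ccna2 leaves out the alternative without overlapping loci.

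In the p53 target list, 4 of 24 genes rose (9 adjusted over the list alone; median log2 0.39, adjusted p = 1.643e-05), a call lost with an estimated correlation (adjusted p = 0.167). Gdf15, a stress-induced secreted factor, rose from 2.75 ± 0.914 to 12.9 ± 2.62 FPKM (log2 1.91, SE 0.27, adjusted p = 0.0038). Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 10.9 ± 2.23 to 40.6 ± 19.2 FPKM (log2 1.72, SE 0.33, adjusted p = 0.0161). The antiproliferative gene Btg2 rose by 1.08 and Trp53inp1 by 1.24. Cdkn1a lost the call without vehicle replicate 1 or 3 (adjusted p 0.0023 to 0.0596 over all alternatives), and Trp53inp1 without any of C26A6 replicates 2 to 4, tamoxifen replicates 2 and 3 or vehicle replicates 1 to 3 (0.0085 to 0.113).

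In the interferon response list, 3 of 41 genes rose (25 adjusted over the list alone; median log2 0.96, adjusted p = 2.570e-14), a call lost with an estimated correlation (adjusted p = 0.356). These were Stat2, a signal transducer of the type I interferon receptor, which rose from 5.88 ± 1.29 to 16.2 ± 4.34 FPKM (log2 1.31, SE 0.20), the regulator Irf7 (log2 1.80) and the GTPase Iigp1 (log2 2.74). In the MHC class I list Tap1 and Tap2 were the 2 of 22 genes that rose (7 adjusted over the list alone; median log2 0.66, adjusted p = 2.199e-04, and 0.467 with an estimated correlation). Irf7 lost the call without C26A6 replicate 2 or vehicle replicate 3 (adjusted p 0.0138 to 0.0898 over all alternatives). With single libraries left out, Iigp1 kept it only without C26A6 replicate 3 or 4 or tamoxifen replicate 1 (0.0201 to 0.121).

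Milk genes rose in 4 of 16 cases (9 higher and 1 lower adjusted over the list alone; median log2 0.73, adjusted p = 2.090e-05), a call lost with an estimated correlation (adjusted p = 0.218). The caseins Csn1s1 and Csn2 rose by 3.30 (SE 0.54) and 3.81 (SE 0.56) on the log2 scale, Csn1s1 from 121 ± 66.2 to 1386 ± 1183 FPKM. With the farthest library of each group left out, 3 together, Csn1s1 missed the threshold (adjusted p 0.0038 to 0.0531 over all alternatives). Csn2 is uncertain because LOC100862376, which rose by 4.19, overlaps it. Xdh, needed for milk fat droplets, rose by 1.46 and the droplet protein Btn1a1 by 2.19. Without C26A6 replicate 2 or vehicle replicate 2, 3 or 4 Btn1a1 missed the threshold (adjusted p 0.0164 to 0.0758 over all alternatives), and without C26A6 replicate 2 or 4 or vehicle replicate 2 or 3 so did LOC100862376 (0.0067 to 0.110).

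Among immediate early genes, 3 of 17 rose (3 adjusted over the list alone; median log2 0.36, adjusted p = 0.0025, and 0.195 with an estimated correlation). These were Fos (log2 1.07), Zfp36 (0.60) and Dusp1 (1.45), the last overlapping LOC100862171, which rose by 2.15. Fos lost the call without vehicle replicate 3 (adjusted p 0.0039 to 0.0566 over all alternatives) and Zfp36 without C26A6 replicate 2 or 3 or vehicle replicate 2 or 3 (0.0094 to 0.0864). In the heat shock list 4 of 15 genes fell (7 adjusted over the list alone; median log2 -0.11, adjusted p = 0.0032), a call lost with an estimated correlation (adjusted p = 0.0717). The mitochondrial chaperonin Hspd1 fell from 189.7 ± 8.41 to 109.7 ± 11.3 FPKM (log2 -0.79, SE 0.12). The others were the chaperone gene Hsp90aa1 (log2 -0.69, at an overlapping locus) and the cochaperone genes Ahsa1 (-0.56, adjusted p = 0.0437) and Chordc1 (-0.48, adjusted p = 0.0485). Hsp90aa1 lost the call without C26A6 replicate 2 or vehicle replicate 1 or 3 (0.0052 to 0.0632). With single libraries left out, Ahsa1 kept it only without C26A6 replicate 1, tamoxifen replicate 1 or vehicle replicate 2 (0.0044 to 0.134), and Chordc1 only without C26A6 replicate 4 or tamoxifen replicate 1 (0.0164 to 0.130).

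Some moved genes belonged to lists that did not pass with camera, although the estrogen receptor list was lower with fry (adjusted p = 0.0185). Scd1, which desaturates fatty acids, rose from 227 ± 75.6 to 777 ± 200 FPKM (log2 1.80, SE 0.32), while the elongase Elovl6 fell by 1.20. Of the estrogen receptor list, the receptor gene Esr1 rose by 1.31, and its targets Myc and Ccnd1 fell by 1.30 and 1.17. Myc missed the threshold without C26A6 replicate 2 or vehicle replicate 3 (adjusted p 0.0065 to 0.0572 over all alternatives). Ccnd1 missed it without C26A6 replicate 1, 2 or 3 or any vehicle replicate (0.0078 to 0.141), and Esr1, with single libraries left out, kept it only without tamoxifen replicate 1 or 4 or vehicle replicate 2 (0.0246 to 0.104). Outside the lists, Rgs1, a regulator of G protein signalling in leukocytes, rose from 1.74 ± 0.834 to 18.8 ± 9.20 FPKM (log2 2.78), and the non-coding RNA Snhg11 rose by 2.33.

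Markers of other cells moved as well. All 5 measured genes of the erythroid list fell (5 adjusted over the list alone; median log2 -5.02, adjusted p = 3.223e-13, and 0.0355 with an estimated correlation). Hbb-b1 stood at 706 ± 246 FPKM with vehicle and 6.56 ± 7.63 with C26A6 (log2 -6.96, SE 0.56), and Beta-s, Hba-a1 and Hba-a2 fell by 7.03, 4.98 and 5.02. These globin genes have near-identical copies, so the share of each is uncertain. The fifth gene, Alas2, which starts haem synthesis in red cell precursors, fell from 3.37 ± 1.31 to 0.476 ± 0.260 FPKM. Alas2 was in the list as fixed in advance, but was chosen for naming here after its values were seen. The fibroblast and matrix list was lower (median log2 -0.80, adjusted p = 1.990e-04, and 0.616 with an estimated correlation), although 0 of its 20 genes passed at either adjustment. Tagln, a smooth muscle gene of the basal list, was listed at 0 in 3 C26A6 libraries and at 10.04 FPKM in the other, against 12.5 to 15.5 with vehicle. Its call was lost without C26A6 replicate 1, 2 or 4 or any vehicle replicate (adjusted p 2.425e-04 to 0.12 over all alternatives), and the basal list did not pass (adjusted p = 0.0861, and 0.356 with an estimated correlation). Phtf1 was listed at 0 in every C26A6 library and Rffl in every vehicle library, and all 3 loci overlap another annotated locus.

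**Figure D2:**
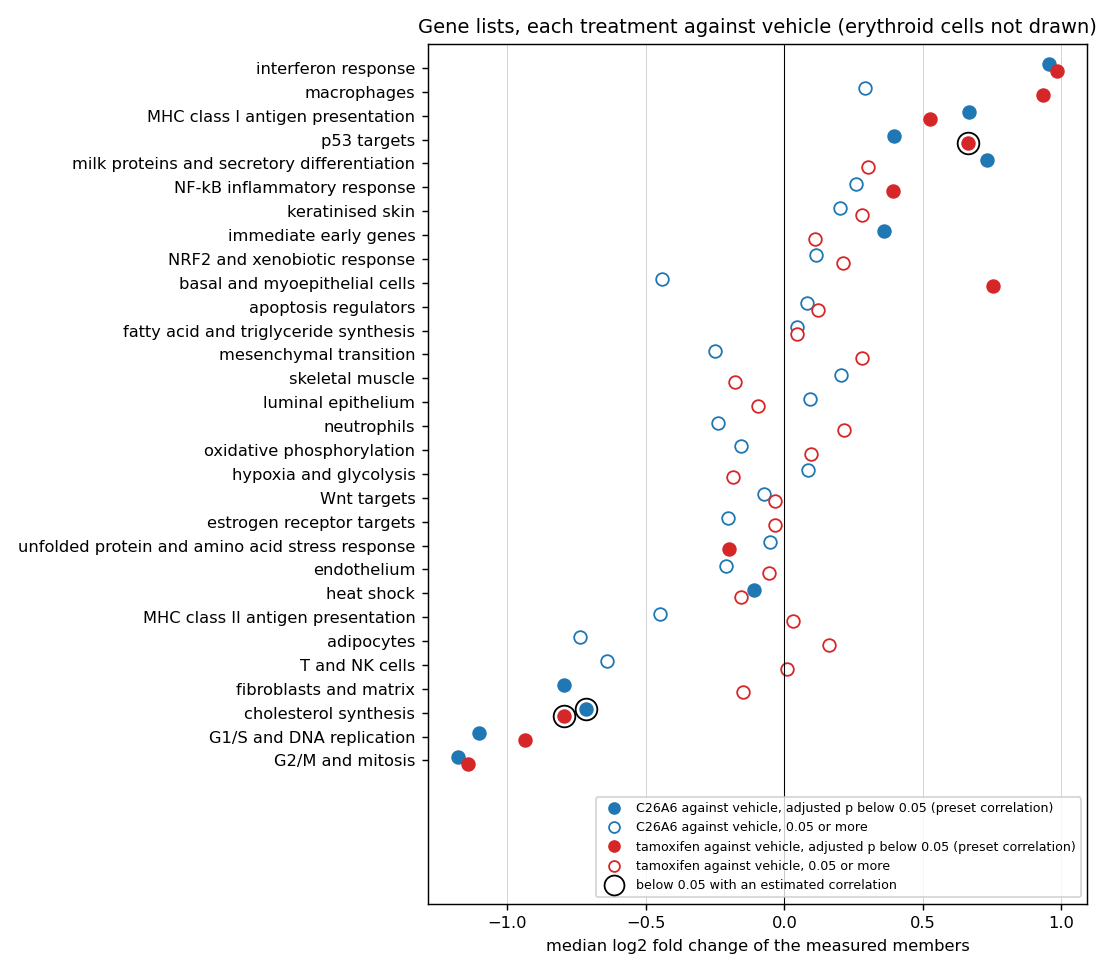
Median log2 fold change of 30 gene lists for C26A6 (blue) and tamoxifen (red) against vehicle. Filled points mark an adjusted p below 0.05 with the preset correlation and rings those that held with an estimated one, which besides the erythroid list, not drawn, were cholesterol synthesis in both comparisons and p53 targets with tamoxifen.

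The comparison of tamoxifen with vehicle addressed the acute deletion of Mtdh, with tamoxifen itself present in the same animals. Genes of cholesterol synthesis, DNA replication and mitosis and haemoglobin transcripts were lower, and some p53 target (7 of 24), interferon response (2 of 41) and macrophage genes (4 of 17) higher. As lists, cholesterol synthesis, erythroid and p53 genes held with an estimated correlation, and replication, mitosis, interferon and macrophages did not (adjusted p between 0.169 and 0.334). With fry, adjusted p was 0.0064 for replication, 0.0077 for mitosis and 0.0288 for macrophages. It was 0.026 for basal genes and 0.0168 for the NF-kB list. Fry gave 0.0627 for interferon, 0.0721 for MHC class I and 0.0554 for unfolded protein stress, which did not pass. Of 12848 genes, 301 passed the threshold, 137 higher and 164 lower, and 159 changed more than 2-fold. With the FPKM as deposited, 338 passed, 107 higher and 231 lower. The count was 95, 65 and 84 without tamoxifen replicate 1, 2 and 3 and 154, 100 and 43 without vehicle replicate 1, 2 and 3.

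The p53 list showed 7 of 24 genes higher (15 adjusted over the list alone; median log2 0.66, adjusted p = 2.756e-13), and the call held with an estimated correlation (adjusted p = 0.0230). Gdf15 rose from 2.75 ± 0.914 to 19.8 ± 7.89 FPKM (log2 2.43, SE 0.27, adjusted p = 0.0011) and Cdkn1a from 10.9 ± 2.23 to 64.2 ± 21.1 FPKM (log2 2.40, SE 0.33, adjusted p = 0.0050). Btg2 rose by 1.01. The death receptor gene Fas rose from 2.58 ± 1.31 to 7.47 ± 1.31 FPKM (log2 1.30), and lost the call without tamoxifen replicate 1 or 2 or vehicle replicate 3 (adjusted p 0.0048 to 0.0748 over all alternatives).

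Cholesterol synthesis genes fell in 11 of 22 cases (17 adjusted over the list alone; median log2 -0.80, adjusted p = 3.657e-17), and the call held with an estimated correlation (adjusted p = 0.0196). Fdps fell from 105 ± 17.2 to 38.6 ± 3.62 FPKM (log2 -1.41, SE 0.15, adjusted p = 0.0011). The mevalonate decarboxylase Mvd fell by 1.14, Stard4 by 1.37 and Insig1, a sterol sensor, by 1.54. These 4 passed under every alternative.

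Of the G1/S and DNA replication list 17 of 35 genes fell (34 adjusted over the list alone; median log2 -0.94, adjusted p = 8.271e-26, and 0.169 with an estimated correlation). Of the G2/M and mitosis list 18 of 36 fell (36 adjusted over the list alone; median log2 -1.14, adjusted p = 7.979e-29, and 0.169 with an estimated correlation). Ccna2 fell from 48.2 ± 3.65 to 19.5 ± 3.96 FPKM (log2 -1.28, SE 0.21), Bub1b by 1.46, Gins1 by 1.26, Uhrf1 by 1.60 and the mitotic kinase Plk1 by 1.57. Without vehicle replicate 3 each of these 5 missed the threshold (adjusted p = 0.0581, 0.0574, 0.0538, 0.0864 and 0.0692, each the highest of any alternative, with lowest values of 0.0019 to 0.0053). Uhrf1 and Plk1 also missed it without tamoxifen replicate 1, 2 or 3, and Uhrf1 without vehicle replicate 2.

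Interferon response genes were higher as a list (median log2 0.99, adjusted p = 1.912e-15, and 0.334 with an estimated correlation), with 2 of 41 past the threshold and 22 adjusted over the list alone. Irf7 rose from 17.15 ± 6.197 to 67.3 ± 17.9 FPKM (log2 1.96, SE 0.36), and the antiviral GTPase Mx2 rose by 1.20. In the MHC class I list 3 of 22 genes rose (5 adjusted over the list alone; median log2 0.53, adjusted p = 1.213e-05, and 0.341 with an estimated correlation), namely Tap1, the light chain gene B2m (log2 1.63, at a locus that overlaps another) and H2-T22 (log2 1.41), which has near-identical relatives and is uncertain. Irf7 lost the call without tamoxifen replicate 1 or 2 or vehicle replicate 2 or 3 (adjusted p 0.0094 to 0.0938 over all alternatives) and Mx2, with single libraries left out, kept it only without C26A6 replicate 2 or 3 (0.0197 to 0.136). B2m lost it without any tamoxifen replicate or vehicle replicate 2, 3 or 4 (0.0217 to 0.102), and H2-T22 without tamoxifen replicate 1 or 2 or the same vehicle replicates (0.0179 to 0.121).

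Macrophage markers rose in 4 of 17 cases (10 adjusted over the list alone; median log2 0.93, adjusted p = 5.854e-08), a call lost with an estimated correlation (adjusted p = 0.242). The complement genes C1qc and C1qb rose by 1.07 and 1.21, C1qc from 64.4 ± 13.0 to 140.1 ± 45.2 FPKM. The receptor kinase Mertk rose by 1.14 and the antibody receptor Fcgr1 by 0.93, while the locus of C1qb overlaps another. Each of the 4 calls was lost without tamoxifen replicate 2 or 3 or vehicle replicate 2, 3 or 4, and at least 1 of them without each other library (adjusted p 0.0043 to 0.136 over all alternatives). C1qb lost its call under 20 of 27 alternatives, among them FPKM as deposited, upper-quartile scaling, quantile normalization and a pseudocount of 0.1. With the FPKM as deposited Fcgr1 and Mertk lost theirs too, and with quantile normalization C1qc. Basal and myoepithelial genes were higher as a list (median log2 0.75, adjusted p = 0.0129, and 0.187 with an estimated correlation), with 0 of 12 past the threshold and 2 adjusted over the list alone. With a mean FPKM of at least 5 that list and the NF-kB list missed the threshold (adjusted p 0.0029 to 0.093 and 0.0017 to 0.0905 over all alternatives).

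The NF-kB list was higher (1 of 21 genes, and 3 higher and 1 lower adjusted over the list alone; median log2 0.39, adjusted p = 0.0140, and 0.187 with an estimated correlation). Its gene was Vcam1, an adhesion molecule, which rose by 1.82 and lost the call without C26A6 replicate 1 or 4, tamoxifen replicate 1, 2 or 3 or vehicle replicate 2, 3 or 4 (adjusted p 0.0131 to 0.119 over all alternatives). The list for unfolded protein and amino acid stress was slightly lower (1 of 25 genes, and 5 lower and 1 higher adjusted over the list alone; median log2 -0.20, adjusted p = 0.0453, and 0.259 with an estimated correlation). That call was lost without C26A6 replicate 2 or 3, tamoxifen replicate 2 or 3 or vehicle replicate 1, 3 or 4 (adjusted p 0.0051 to 0.189 over all alternatives). Its gene Shmt2, a mitochondrial enzyme of serine metabolism at an overlapping locus, fell by 0.70, and lost the call without tamoxifen replicate 1, 2 or 4 or vehicle replicate 1, 2 or 3 (0.0213 to 0.110).

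All 5 erythroid genes fell with tamoxifen (5 adjusted over the list alone; median log2 -5.51, adjusted p = 1.159e-15, and 0.0196 with an estimated correlation). Hbb-b1 fell by 8.24 (SE 0.56) to 1.47 ± 1.44 FPKM, and Alas2 by 1.44, the latter missing the threshold without vehicle replicate 3 (adjusted p 0.0019 to 0.0644 over all alternatives). Among single genes, the cytosolic chaperone Hsp90ab1 fell from 766 ± 108 to 255 ± 47.2 FPKM (log2 -1.59, SE 0.27), a call lost without tamoxifen replicate 2 or vehicle replicate 3 (0.0018 to 0.0644). The nuclear receptor gene Nr1h5 fell from 7.74 ± 1.46 to 0.877 ± 0.225 FPKM (log2 -2.21). Rpl29 rose from 2.44 ± 0.905 to 20.8 ± 6.62 FPKM (log2 2.66, SE 0.25), which is uncertain because ribosomal protein genes have many near-identical copies. LOC100862295, on chromosome 15 at 10493164 to 10493909 at a locus that overlaps another, was listed at 0 in all 8 libraries of the other groups and at 8.24, 15.1, 8.80 and 9.39 FPKM in the tamoxifen libraries.

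**Figure D3:**
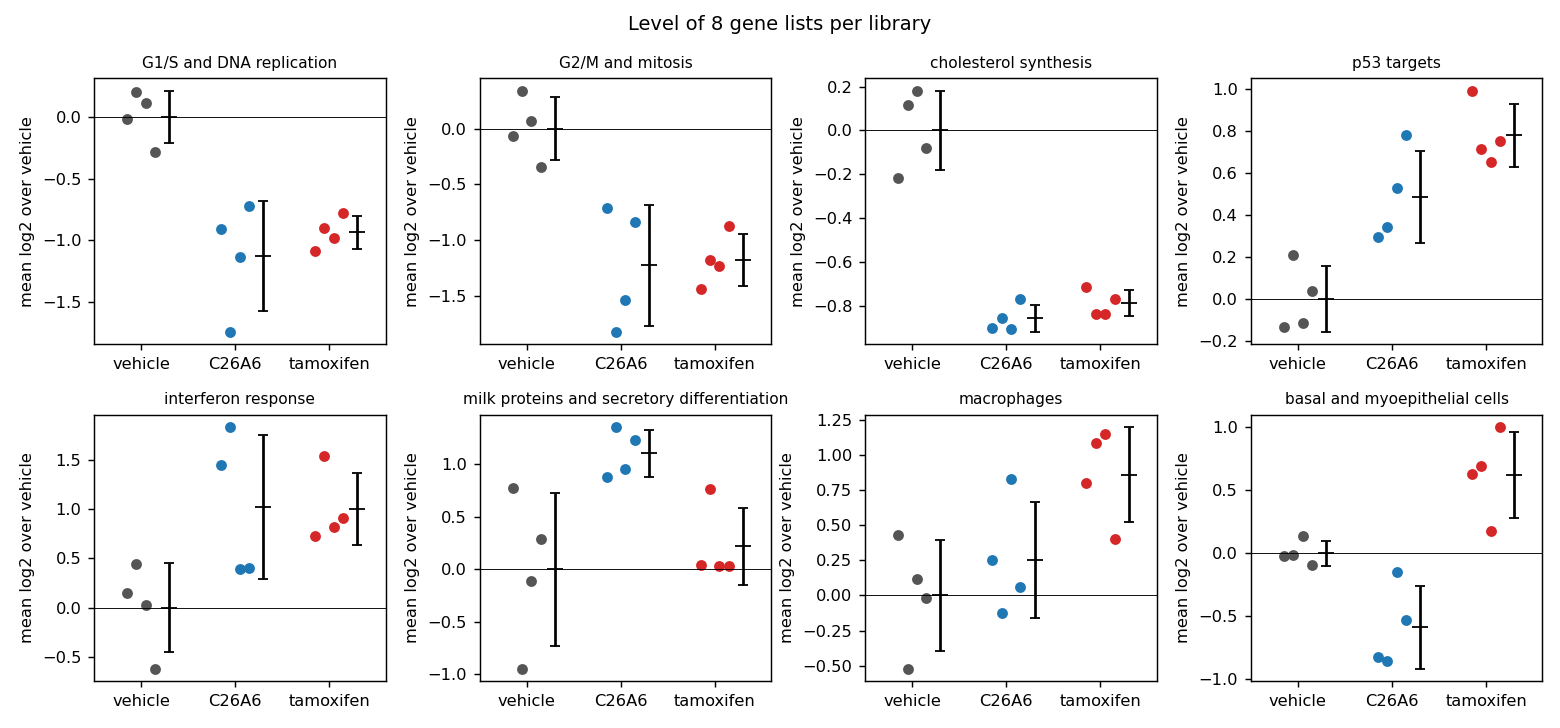
Mean log2 level of 8 gene lists per library relative to the vehicle mean, with 1 point per library and bars for the mean ± SD of 4 libraries. The 4 vehicle libraries lie apart from all treated libraries in both cell cycle lists and in cholesterol synthesis.

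Other lists did not pass the threshold with camera against vehicle in either comparison. With C26A6 and tamoxifen respectively, adjusted p was 0.293 and 0.143 for apoptosis regulators, 0.376 and 0.259 for the NRF2 response, 0.293 and 0.970 for estrogen receptor targets, 0.683 and 0.588 for Wnt targets, 0.984 and 0.261 for luminal epithelium, 0.261 and 0.588 for endothelium and 0.385 and 0.602 for adipocytes. It was 0.692 and 0.970 for skeletal muscle, 0.705 and 0.602 for keratinised skin, 0.705 and 0.706 for neutrophils, 0.213 and 0.781 for T and NK cells, 0.786 and 0.540 for fatty acid synthesis, 0.0599 and 0.838 for MHC class II, 0.385 and 0.123 for mesenchymal transition, 0.465 and 0.118 for hypoxia and 0.0542 and 0.588 for oxidative phosphorylation. Median and test differed in sign for luminal epithelium with C26A6 and for neutrophils, T and NK cells and fatty acid synthesis with tamoxifen, and median and mean for estrogen receptor targets with tamoxifen. With fry, estrogen receptor targets were lower with C26A6 (adjusted p = 0.0185). The list for B and plasma cells had 4 measured genes and was not tested. Lists that passed against vehicle with 1 treatment only had medians of the same sign with the other, except the basal list. With C26A6, median and adjusted p were 0.29 and 0.142 for macrophages, 0.26 and 0.105 for NF-kB and -0.05 and 0.432 for unfolded protein stress. With tamoxifen they were 0.30 and 0.123 for milk genes and -0.16 and 0.2035 for heat shock. They were 0.11 and 0.2035 for immediate early and -0.15 and 0.781 for fibroblast genes.

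The direct comparison of both treatments asked where they differed. Caseins were higher with C26A6, and Mtdh as well, while Gpr34, a receptor of microglia and macrophages, and a few other genes were lower. Only 19 genes passed the threshold, 6 higher and 13 lower with C26A6, and 14 differed more than 2-fold, while 2244 had an unadjusted p below 0.05. With quantile normalization the split was 9 higher and 8 lower of 17. The count was 12, 7, 50 and 8 without C26A6 replicate 1, 2, 3 and 4, then 9 without tamoxifen replicate 2, and 10, 61, 11 and 10 without vehicle replicate 1, 2, 3 and 4.

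Csn1s1 was 5.05 higher with C26A6 than with tamoxifen on the log2 scale (SE 0.54, adjusted p = 0.0017), with 31.6 ± 6.58 FPKM in the tamoxifen group. With the farthest library of each group left out, 3 together, this call and those of H2-T9 and Rpl29 were lost (highest adjusted p of any alternative 0.0584, lowest 2.854e-04, 0.0022 and 8.675e-04). Csn2 was 4.10 higher (SE 0.56), a call lost without C26A6 replicate 2 or 4 (adjusted p 0.0035 to 0.0883 over all alternatives). Mtdh was 2.33 higher (SE 0.20, adjusted p = 2.732e-04). H2-T9 was 2.604 higher and uncertain for its near-identical relatives. Gpr34 stood at 3.41 ± 0.806 FPKM with C26A6 and 16.7 ± 3.71 with tamoxifen (log2 -1.99, SE 0.24, adjusted p = 0.0051), at a locus that overlaps another, and Rpl29 was 2.32 lower. The oxytocin receptor gene Oxtr was 1.96 lower, and lost the call without C26A6 replicate 1, 2 or 4, tamoxifen replicate 1 or 2 or vehicle replicate 1 or 4 (adjusted p 0.0098 to 0.126 over all alternatives). The lipid transporter gene Abca7 was 0.85 higher, and Ch25h, which hydroxylates cholesterol, and the Notch target Hey2 were 1.68 and 1.16 lower. With single libraries left out, Abca7 kept the call only without C26A6 replicate 3 or vehicle replicate 2 (0.0134 to 0.118), Ch25h only without tamoxifen replicate 3 or vehicle replicate 2 (0.0122 to 0.137) and Hey2 only without C26A6 replicate 3, tamoxifen replicate 4 or vehicle replicate 2 (0.0177 to 0.123). For Tap1, Tap2 and Snd1 the log2 differences between treatments were 0.11 (95% interval -0.40 to 0.62), 0.20 (-0.13 to 0.53) and 0.09 (-0.21 to 0.40), none past the threshold.

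By lists, basal and myoepithelial genes were lower with C26A6 than with tamoxifen (1 of 12, Oxtr, and 6 adjusted over the list alone; median log2 -1.16, adjusted p = 9.329e-05), a call lost with an estimated correlation (adjusted p = 0.129). Also lower were fibroblast genes (0 of 20, and 0 adjusted over the list alone; median log2 -0.92, adjusted p = 4.010e-04), macrophage genes (0 of 17, and 1; -0.68, 4.010e-04), MHC class II (0 of 9, and 2; -0.78, 0.0184), mesenchymal transition (0 of 16, and 1; -0.45, 0.0108), oxidative phosphorylation (0 of 34, and 0; -0.29, 0.0053) and p53 targets (0 of 24, and 3; -0.23, 0.0053). Higher were milk genes (2 of 16, and 5 higher and 1 lower adjusted over the list alone; median log2 0.66, adjusted p = 0.0184), hypoxia (0 of 26, and 1; 0.22, 0.0108) and immediate early genes (0 of 17, and 0; 0.30, 0.0472). All of these calls were lost with an estimated correlation (adjusted p between 0.739 and 0.807 for those after the basal list). With fry the basal list passed (adjusted p = 0.0031) and the other lists named here did not. Fry also gave lower heat shock and estrogen receptor target lists with C26A6 (adjusted p = 0.0284 each), which did not pass with camera (0.0621 and 0.254). With the preset correlation, MHC class II and mesenchymal transition also lost theirs without C26A6 replicate 2 or tamoxifen replicate 2 (adjusted p 6.666e-04 to 0.135 and 3.296e-04 to 0.125 over all alternatives), milk genes without C26A6 replicate 2 or tamoxifen replicate 4 (8.587e-04 to 0.0783), hypoxia without C26A6 replicate 1 (1.398e-04 to 0.412) and oxidative phosphorylation without tamoxifen replicate 1 (1.818e-04 to 0.708). Immediate early genes lost it without C26A6 replicate 1 or 3, tamoxifen replicate 3 or 4 or vehicle replicate 1 or 2 (0.0031 to 0.273). With the adipocyte level as covariate, MHC class II and hypoxia lost theirs (0.0702 and 0.095). With library weights or with the farthest library of each group left out, so did fibroblast genes (2.427e-07 to 0.0783 over all alternatives), and with the latter p53 targets (1.398e-04 to 0.0576). Median and test differed in sign for MHC class I, the NRF2 response and Wnt targets, which did not pass.

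Both treatments moved many genes in the same direction. Against vehicle, 169 genes passed in both comparisons, 50 higher and 119 lower, and 0 in opposite directions. Among them were Gdf15, Cdkn1a, Btg2, Irf7 and Tap1, which rose, and Fdps, Stard4, Uhrf1, Ccna2, Bub1b, Nr1h5 and the globin genes, which fell. Independent lists of these sizes would share 2.39 higher and 4.58 lower genes, but comparisons with the same vehicle libraries are not independent. In simulations of all 12 libraries with no change in any group, both comparisons shared 0.01 genes on average. With no change put in, few calls can be expected, so this value is no reference for treatments that each change genes. When the 4 vehicle libraries were split so that each treatment had its own 2, between 11 and 23 genes passed in both over the 6 splits. The fold changes of all genes correlated with r = 0.553 across genes, which are not independent replicates, against 0.552 in the simulated unchanged groups, and their covariance was 0.119 against a mean of 0.060 and a maximum of 0.260 simulated. The share of genes with the same sign was 63.9%, against 69.6% simulated. With the FPKM as deposited the shared genes were 205, 32 higher and 173 lower. Their number was 108 without C26A6 replicate 3, then 63, 50 and 54 without tamoxifen replicate 1, 2 and 3, and 65, 60 and 26 without vehicle replicate 1, 2 and 3.

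**Figure D4:**
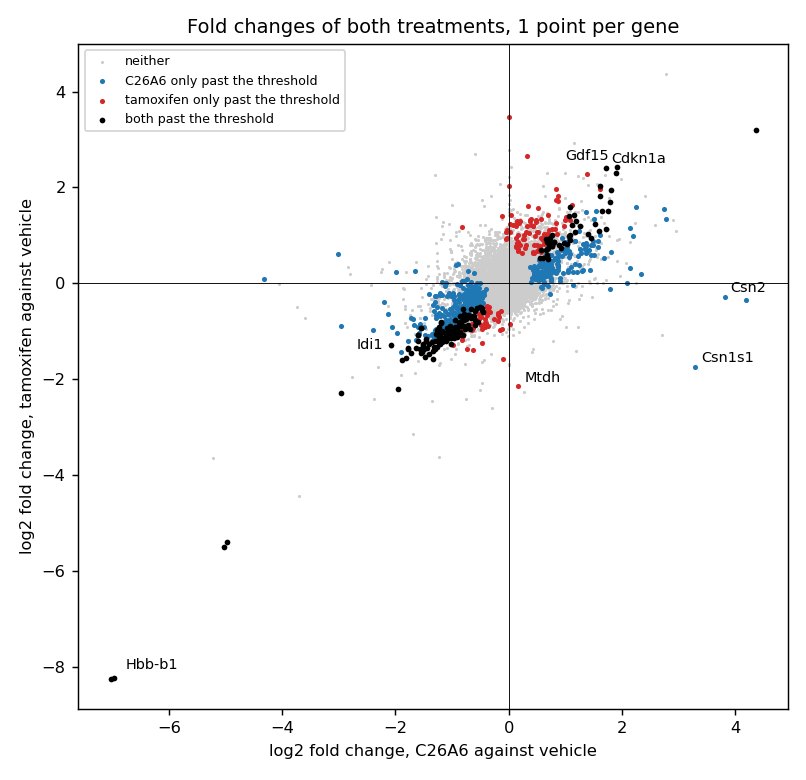
Log2 fold change against vehicle of each gene with C26A6 (horizontal axis) and tamoxifen (vertical axis), 1 point per gene, coloured by the comparisons in which it passed the threshold. The 169 genes past it in both (black) lie in the 2 quadrants of equal sign, and Mtdh fell with tamoxifen alone, a difference of 2.33 between the treatments.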

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

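The tests on globin copies, on fat content, on depth and on the genes listed at 0, and the comparison of clock arms with the spread of their members, were chosen after the results were seen, while those on blood, on time of day and on other splits of the libraries were planned. A library was singled out when its gap to the nearest library of its group, divided by the range of the group, exceeded 0.829 (Dixon's critical value for 4 libraries). Chance marks about 5% of groups, and 15 of the 300 groups tested were marked, the number that chance alone gives. No library was marked more than 3 times.

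Among genes, the ratio was 0.938 for B2m with C26A6 (replicate 4 at 974.8 FPKM, the others at 1469 to 1509), 0.859 for Beta-s with tamoxifen (replicate 1 at 4.05, the others at 0.670 to 0.952) and 0.894 for Ccr2 with tamoxifen (replicate 2 at 18.1, the others at 2.71 to 3.41). It was 0.848 for Fas with C26A6 (replicate 1 at 2.32, the others at 3.06 to 3.21), 0.952 for Gins1 with tamoxifen (replicate 1 at 1.99, the others at 4.13 to 4.27) and 0.909 for Hsp90aa1 with vehicle (replicate 4 at 228, the others at 276 to 281). It was 0.850 for Oxtr with tamoxifen (replicate 4 at 34.7, the others at 11.3 to 13.4), 0.937 for Rffl with tamoxifen (replicate 2 at 0, the others at 15.9 to 19.4), 0.898 for Snhg11 with vehicle (replicate 3 at 2.85, the others at 0.801 to 0.946) and 1 for Tagln with C26A6 (replicate 3 alone above 0). Among list means, it was 0.905 for immediate early genes and 0.979 for milk genes with tamoxifen (replicates 4 and 2), 0.962 for fibroblast genes with vehicle (replicate 2), and 0.876 and 0.850 for hypoxia with vehicle (replicate 2) and tamoxifen (replicate 4).

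Genes left out of the comparisons also held a signal. When short RNAs and genes with failed estimates were kept, 15 of them passed the threshold for C26A6 against vehicle and 9 for tamoxifen against vehicle. Ldlr, the receptor that takes up cholesterol-carrying lipoprotein, was lower with both treatments (log2 -1.50 and -1.34), as was Plk4, a kinase of centriole duplication (-1.03 and -0.96). The estimate of each had failed in at least 1 library.

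Haemoglobin transcripts were lower in both treated groups than with vehicle. A shift of reads among the 4 globin genes listed does not account for this. Their summed FPKM was 161 times higher with vehicle, with the lowest vehicle library at 936 and the highest treated library at 43.0. A shift to globin copies without an entry could not be checked. Less blood in the treated tumours may contribute, because the FPKM summed over 13 other red cell genes was also lower in the treated libraries (two-sided exact permutation p = 0.0202 over 495 arrangements), although Klf1 and Rhd were higher with C26A6, Gata1 with tamoxifen and Trim58 with both. The sum was 1.27 ± 0.705 with vehicle, 0.754 ± 0.172 with C26A6 and 0.537 ± 0.241 with tamoxifen, a far smaller change than that of the globins. These 13 genes were near the floor, the highest group mean being 0.304 FPKM (Slc4a1 with vehicle), so their sum cannot measure how far blood content differed. Vehicle replicate 1 stood highest at 2.26, and vehicle replicate 2 (0.607) lay within the treated range of 0.228 to 0.996. The size of the globin fall stays open. Removal or perfusion of blood that differed between groups was not described in the labels, and a response of the treated tumours was not tested.

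Many genes moved in the same direction with both treatments, which share their vehicle libraries. A different time of day at collection stays open. It was predicted to move both arms of the circadian clock in opposite directions. Their medians, both higher with each treatment, differed by 0.104 with C26A6 and 0.295 with tamoxifen. By the rule planned in advance, differences this small in both comparisons spoke against this cause. The members of an arm, however, spread by up to 0.417 (SD), a check added later, so the medians do not settle it. The clock gene Per1 rose with both treatments (log2 1.45 and 0.95). Arntl, of the other arm, rose with C26A6 (0.68, limma adjusted p = 0.0175) and did not pass with tamoxifen (0.16). With the adipocyte level as a covariate, 168 of the 169 shared genes still passed. The adipocyte list did not pass in either comparison, and its median moved in opposite directions (log2 -0.74 with C26A6 and 0.16 with tamoxifen). A covariate that separates the groups so little could hardly remove shared calls, so fat content was neither shown nor excluded as a cause. All 4 vehicle libraries lay within the depth range of the treated libraries, so depth did not set the vehicle group apart. Smaller effects of depth were not tested. No batch is named in the labels, no group received tamoxifen without the floxed alleles, and none received the solvent of C26A6 alone, so a common effect of dosing or handling is a candidate explanation that was not tested, as is an effect of the Mtdh and Snd1 contact.

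Some genes past the threshold were listed at 0 in every library of 1 group compared, among them Rffl, Phtf1 and LOC100862295. Assignment of reads between overlapping genes is a candidate explanation, since 7 of 7 such genes lay at overlapping loci against 18.7% of the other genes past the threshold (two-sided Fisher exact p = 9.383e-06). Too few reads do not account for them in the first comparison that called each, since the intervals of the FPKM implied at least 21.3 fragments per gene in every library of the group not at 0, while for the call of Rffl with tamoxifen this was not shown, as replicate 2 was at 0 as well. That Rffl call was lost under 18 of 27 alternatives, 11 of them single libraries left out (limma adjusted p 2.074e-08 to 0.189 over all alternatives). A biological explanation for these genes was not tested.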

How the results depend on the processing

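The alternatives with 3 libraries left out together, with the adipocyte covariate and without overlapping loci were chosen after seeing the data. Of 99 named gene results past the threshold, 99 kept their direction and 45 stayed past it under each of the 26 to 28 settings that gave a value for them, while 162 values not past it changed sign, 158 of them for lists. With camera at an estimated correlation 2, 3 and 0 lists passed (C26A6 against vehicle, tamoxifen against vehicle, C26A6 against tamoxifen), and 3 with fry in the last. With no filter on low values 156 genes changed with tamoxifen and 95 with both treatments, and with a mean FPKM of at least 5, 10 differed between treatments. With only the 2 groups compared the counts were 355 for C26A6 against vehicle and 9 for C26A6 against tamoxifen. Library weights gave 1470 genes for C26A6, 1009 for tamoxifen and 542 for both, a correlation of 0.640 and 3 lists between treatments. With 3 libraries far from their group left out together, in each group the farthest (vehicle replicate 2, C26A6 replicate 2 and tamoxifen replicate 1) the counts were 270, 83, 5 and 45, the correlation 0.605 and the lists between treatments 3. There oxidative phosphorylation with tamoxifen reversed to -0.11 (adjusted p = 0.0115) and interferon response between treatments to -0.33 (adjusted p = 0.0174). The adipocyte level as covariate gave 546 genes for tamoxifen, 305 for both and a correlation of 0.630, and with genes at overlapping loci left out 31 genes differed between treatments. The cause was not tested. Leaving out each library in turn gave 128 to 713 genes for C26A6, 43 to 395 for tamoxifen, 7 to 61 between treatments and 26 to 173 for both, lists of 11 to 16, 10 to 12 and 7 to 13, a correlation of 0.472 to 0.603, Mtdh with tamoxifen at -2.23 to -2.01 and Snd1 with tamoxifen at -0.39 to -0.22, whose unadjusted p exceeded 0.05 without tamoxifen replicate 2 or vehicle replicate 3 or 4. The libraries that moved each count are named beside it in the report. With the replicate block, 625, 284 and 24 genes and 12, 11 and 7 lists passed and 141 genes with both. Libraries of the same number did not pair, with correlations of group-centred values from -0.21 to 0.33. What depth limits was not tested apart from the spread between libraries, at which 8% of genes changed by 0.5 on the log2 scale were called in simulation.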

Other observations

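The tests on Reactome sets were chosen after the results were seen, while the counts of other splits were planned. The 8 libraries compared can be split into equal groups in 35 ways. The real split ranked 1 for the gene counts of 583 (C26A6 against vehicle), 301 (tamoxifen against vehicle) and 19 (C26A6 against tamoxifen). The highest other split called 1 gene in each. Rank 1 of 35 is the most extreme outcome possible, so chance is unlikely for each count but not excluded. For the 169 genes of both treatments, 100 groupings of the 12 libraries were tried, the real one and others drawn at random. The highest of the others called 1 gene. Chance accounts well for the number of lists at the preset correlation. There 11, 11 and 10 lists passed, the highest other splits called 17, 18 and 17, and 15, 18 and 15 of 35 splits called as many.

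Of 605 Reactome sets with 15 to 200 members, 231, 149 and 52 passed at the preset correlation (C26A6 against vehicle, tamoxifen against vehicle, C26A6 against tamoxifen) and 0, 9 and 0 with an estimated correlation. The 9 sets all concerned the processing, termination or transport of transcripts. Several of them had identical sizes, medians and p, so they are not separate results. With tamoxifen, mRNA splicing was lower (110 measured genes, median log2 -0.26, 3 called lower, adjusted p = 0.0404 with an estimated correlation), and so was transport of mature transcripts (27 genes, -0.27, 2 called lower, 0.0404). Cholesterol biosynthesis, a Reactome set of 20 measured genes, missed the threshold with an estimated correlation over these sets (adjusted p = 0.0744 with C26A6 and 0.0685 with tamoxifen), unlike the cholesterol list of the report. With C26A6 the splicing set did not pass with an estimated correlation (-0.20, 9 called lower, adjusted p = 0.0717), nor did the circadian clock set (25 genes, 0.38, 3 called higher, 0.0717).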
